A study of Cicer arietinum with 11 samples.

How the data were processed

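Gene expression was measured by sequencing of mRNA libraries from 11 chickpea (Cicer arietinum) samples of the genotype ICC4958, a desi-type line. Per the labels' protocols, seedlings came from a culture room and mature plants from the field, total RNA was isolated with TRI reagent, and libraries were made with an Illumina mRNA-Seq kit. Each sample was 1 tissue or stage with 1 library. 3 groups were formed from the tissue labels: vegetative (germinating seedling, young leaves and the shoot apical meristem of 20-day-old plants, n = 3), flower bud (stages 1 to 4, n = 4) and flower (stages 1 to 4, n = 4). The last 8 are called reproductive below.

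Per the series text, the authors filtered the reads with NGS QC Toolkit, mapped them to a set of 34760 chickpea transcripts and deposited RPKM, reads scaled by transcript length in kilobases and by the mapped reads of the library, for each transcript and sample. Per the same text the authors tested expression with DESeq; those results are not used here. The aligner, its settings and the treatment of reads shared between similar transcripts are not given in the sources used here, so values of near-identical transcripts are uncertain. RPKM divides by each library's total, so a few abundant transcripts in a library lower the values of all others. Each file held 34760 named transcripts and 128 blank rows, which were left out. No gene names accompany the transcript IDs in the files, and 0 of 34760 IDs were found in the reference table of 29938 genes. The gene lists chosen before the data were examined (floral organ identity, meristem, pollen, photosynthesis and others) could therefore not be tested, and no list result is given. The IDs belong to a transcript set, so no genome positions are given.

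Depth was recovered from the values. An RPKM is a whole number of reads divided by transcript length and library total, so ratios of low values between libraries gave the relative depths. The totals were then set so that transcript lengths came out whole, and each length was the shortest of at least 100 bases that made every library's reads whole. A library whose reads came out nearly all as multiples of 2 or 3 had its total divided by that number, a step added after the first total of flower bud 2 proved too large in this way. The minimum of 100 bases was chosen from the data after shorter and longer minimums were tried, because the recovered reads then summed to just under each library total; with longer minimums they exceeded it. All 34703 transcripts with a value above 0 gave whole reads, within 4e-09 of the value plus 3e-06 reads, and the recovered reads summed to 99.952% to 99.998% of the totals. The other 57 transcripts were at 0 throughout. On simulated data of 12000 transcripts the method returned 11 of 11 totals and 99.94% of values exactly. Totals ran from 14536530 to 35643139 reads, a 2.45-fold range, and 1 read in a transcript of the median length of 736 bases was worth 0.0381 to 0.0935 RPKM. Recovered lengths and reads rest on this reconstruction. Floors of 3 reads and 95% Poisson intervals were computed from them, and cover counting error only.

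Groups were compared with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with 1 fit over the 3 groups and an intensity trend in the empirical Bayes step. Transcripts with an RPKM of at least 1 in at least 3 libraries were tested (31776). A transcript was called where the Benjamini-Hochberg adjusted p was under 0.05 and the log2 difference at least 1 in size. Log2 differences are on the log2(RPKM + 1) scale, which understates the change of low transcripts. The reproductive contrast was the mean of the flower bud and flower groups minus vegetative. Another limma fit on the 8 reproductive libraries used the stage order, with flower bud 1 to 4 followed by flower 1 to 4, and reported the fitted change from first to last stage. That the label numbers follow development is an assumption. Because libraries of a group are different tissues or stages and not replicate plants, p-values measure the spread between tissues or stages. In the 3-group fit this spread was 1 estimate pooled over the 3 groups. Flower against flower bud therefore also carries the spread between vegetative tissues, and the vegetative contrasts carry that between reproductive stages.

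On simulated data with 200 of 31776 transcripts changed, the reproductive contrast recovered 81% of changes of 2 on the log2 scale, with 9.5% of calls false, and 98% of changes of 4, with 2.5% false. At a change of 2 the flower bud contrast recovered 75% and the flower contrast 70%. The contrast of flower with flower bud recovered 95.5% of changes of 3, and the stage order 71.5%. These rates describe the simulated data only. The real vegetative tissues were less alike (mean Spearman correlation of 0.771) than flower buds (0.917) or flowers (0.920). The rates may not reflect this unequal spread, and they need not hold for low transcripts. Recovery and false calls in the real contrasts are therefore not known.

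Numbers of detected transcripts (RPKM of at least 1) and the share of summed RPKM in the 100 highest transcripts were compared with two-sided exact permutation tests, adjusted over 4 comparisons. Class separation was the mean Spearman correlation within groups minus that between groups, tested over all 5775 regroupings. Without a test, as descriptions, the following were counted. Library-specific transcripts had an RPKM of at least 5 and at least 5 times that of every other library. Reproductive-only transcripts had an RPKM of at least 1 in at least 3 reproductive libraries and under 0.1 in all 3 vegetative ones; vegetative-only transcripts had at least 1 in all 3 vegetative libraries and under 0.1 in all 8 others. Steps were differences of at least 2 in log2(RPKM + 1) between consecutive stages. These counts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

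The transcripts named for each limma comparison were the 2 with the largest positive and the 2 with the largest negative log2 difference past the threshold whose libraries did not overlap between the groups compared, or the largest fitted change for the stage order. This rule, the tests and the alternatives listed next were fixed before the data were examined. These were a pseudocount of 0.1, no filter, a mean RPKM of at least 5, median-of-ratios scaling, quantile normalization, no intensity trend, fits on 2 groups only, stage number as a block, stage number within class, other thresholds for the counts, and leaving out each library in turn. Chosen after seeing the data were limma voom on the recovered reads, a filter of at least 10 recovered reads in 3 libraries, and thinning of all libraries to 14536530 reads. A count model was not used as the main test, since the deposited values are RPKM.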

Results

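The series profiled transcripts through chickpea flower development against vegetative tissue. It held 11 mRNA libraries: 3 vegetative tissues (germinating seedling, young leaves, shoot apical meristem), 4 flower bud stages and 4 flower stages. Library totals recovered from the RPKM values were 23927246 reads for the germinating seedling, 27158340 for young leaves and 31511021 for the shoot apical meristem. Flower buds 1 to 4 had 33854669, 14536530, 35643139 and 29706745, and flowers 1 to 4 had 24784511, 29207580, 20366054 and 24950732. Flower bud 2 was the shallowest library. There was 1 library per tissue or stage, so errors and p-values below describe the spread between tissues or stages. In the 3-group limma fit that spread was pooled over the 3 groups. The files do not pair transcript IDs with gene names, so transcripts are given by ID alone and what they encode is not stated.

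Most transcripts were shared across the plant: 21322 of 34760 (61.3%) reached an RPKM of 1 in all 11 libraries, and 1011 did so in exactly 1. The germinating seedling expressed the most transcripts at that level (30066) and young leaves the fewest (27059). The mean was 28904 ± 1616 (SD, n = 3) in vegetative libraries, 29059 ± 243 (SD, n = 4) in flower buds and 28562 ± 727 (SD, n = 4) in flowers. No group difference passed the two-sided exact permutation test, with adjusted p of 0.93 for reproductive against vegetative and 0.80 for flower against flower bud. For comparisons with 4 libraries in each group, or 3 and 4, the smallest possible exact permutation p is 0.0286, so a single such difference among the 4 comparisons cannot pass after adjustment. At an RPKM of at least 5, every flower had fewer transcripts than every flower bud, with a mean difference of -1199.5 (exact permutation p = 0.0286, adjusted p = 0.114). At least 10 reads after thinning, a setting chosen after seeing the data, gave -815 (exact permutation p = 0.0571, adjusted p = 0.229). Leaving out the germinating seedling moved the reproductive minus vegetative difference from -93.7 to 487 transcripts, leaving out the shoot apical meristem to 248, and leaving out flower 3 to 93.0. The flower bud minus vegetative difference went from 155 to -768 without young leaves, and the flower minus vegetative difference from -342 to 239 without the germinating seedling and to 10.7 without flower 3.

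Young leaves had the most uneven transcript makeup, with 40.2% of summed RPKM in their 100 highest transcripts and 35550 RPKM in Ca_TC23009 alone, a transcript picked here after its values were seen. The share was lowest in flower bud 1, at 15.4%. As a share of reads, the 100 highest transcripts held 16.6% in young leaves, again the most. The lowest share of reads was 6.8%, in the shoot apical meristem, with 7.8% in flower bud 1. Group means of the RPKM share were 26.4% ± 12.5 (SD, n = 3) in vegetative libraries, 18.8% ± 2.59 (SD, n = 4) in flower buds and 21.3% ± 3.59 (SD, n = 4) in flowers. The difference of reproductive from vegetative libraries was -6.33 percentage points, with an adjusted p of 0.51 in the two-sided exact permutation test, and it was 0.58 without young leaves. The flower minus vegetative difference was -5.08 points and became 1.83 without young leaves.

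Libraries of a class resembled each other more on average than those of other classes, by little for the vegetative tissues. The mean Spearman correlation across transcripts was 0.917 between flower buds (6 pairs), 0.920 between flowers (6 pairs) and 0.771 between vegetative tissues (3 pairs). Vegetative pairs ran from 0.741 to 0.790 and pairs of a vegetative tissue with a flower bud from 0.730 to 0.786, so the ranges overlapped. Pairs of a flower bud and a flower reached 0.930, above the lowest pairs within flower buds (0.881) and within flowers (0.887). Flower buds and flowers correlated at 0.846 on average over 16 pairs, while vegetative libraries correlated at 0.759 with flower buds and 0.749 with flowers. The mean correlation within classes exceeded that between classes by 0.098, the largest value among 5775 regroupings (exact permutation p = 0.00017, the smallest they can give). Correlations here are across transcripts, which are not independent replicates.

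**Figure D1:**
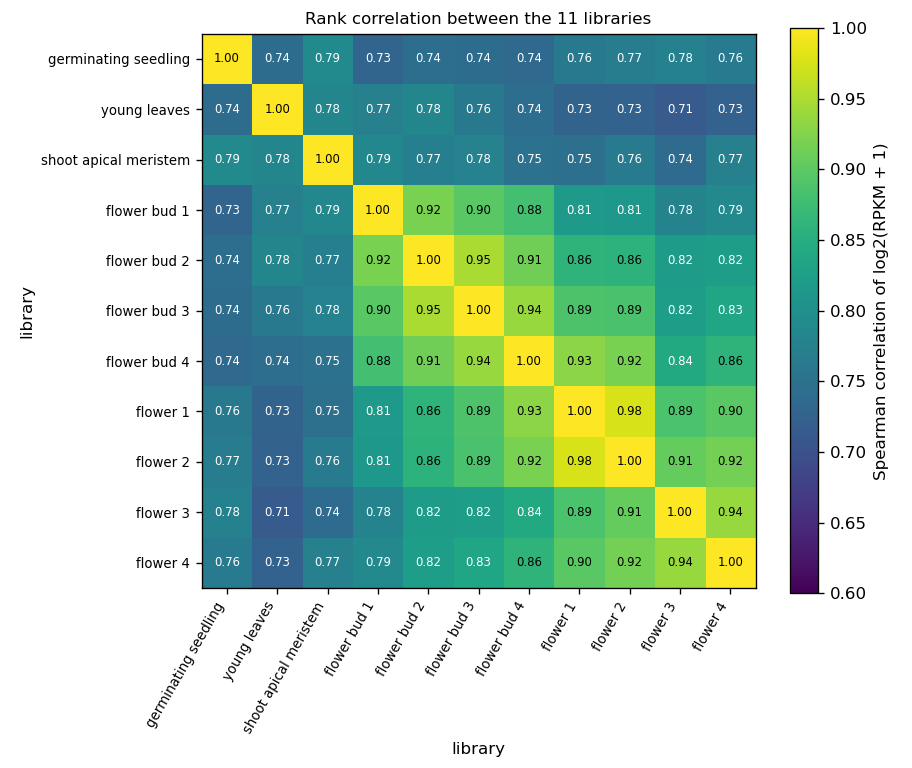
Spearman correlation of log2(RPKM + 1) across 34760 transcripts for each pair of the 11 libraries, as a colour scale that starts at 0.6, with values printed in the cells. Flower 1 and flower 2 are the closest pair at 0.976, and young leaves and flower 3 the most distant at 0.715.

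The comparison of reproductive with vegetative libraries asks which transcripts are preferentially expressed during flower development. Seedlings came from a culture room and mature plants from the field, so growing site and plant age may run with class. In all comparisons with vegetative libraries their part cannot be told apart from that of tissue. More transcripts were called higher than lower: 1748 higher and 719 lower in the 8 reproductive libraries, of 31776 tested with limma. Vegetative tissues were less alike (mean Spearman correlation of 0.771) than flower buds (0.917) or flowers (0.920). A transcript high in only 1 vegetative tissue varies within its group and is less easily called lower. The balance of calls against vegetative tissue therefore need not show how many transcripts rise or fall. Without young leaves 52.5% of calls were higher. Changes of at least 4-fold were mostly increases, with 741 higher and 137 lower. Ca_TC08771 had 1.01 ± 1.18 RPKM (SD, n = 3) in vegetative libraries, 2035 ± 1293 (SD, n = 4) in flower buds and 1940 ± 863 (SD, n = 4) in flowers, a log2 difference of 9.90 ± 0.56 (SE; limma, adjusted p = 1.04e-06). Ca_TC11813 had 0 reads in all 3 vegetative libraries and 1310 ± 824 (SD, n = 4) RPKM in flower buds and 929 ± 457 (SD, n = 4) in flowers. Against a floor of 3 reads over the 82596607 vegetative reads, its mean over the reproductive libraries was at least 58979-fold higher. Flower 3, its lowest reproductive library, gives at least 15719-fold. Ca_TC08771 and Ca_TC11813 were both highest in flower bud 4, at 3726 and 2406 RPKM.

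Among transcripts that fell, Ca_TC16732 had 1083 RPKM in the germinating seedling, 153 in the shoot apical meristem and 11.99 in young leaves, and at most 3.04 in any reproductive library. Its log2 difference was -5.58 ± 0.93 (SE; limma, adjusted p = 0.00392), with -4.042 without the germinating seedling and -7.234 without young leaves. Ca_TC01499 had 578, 24.8 and 2.26 RPKM in the same 3 tissues and 0 reads in all 8 reproductive libraries, so its reproductive level was at least 4441-fold lower against a floor of 3 reads over the 213049960 reads of those libraries. This bound rests on the germinating seedling: without it the vegetative mean gives at least 297-fold, and young leaves alone at least 49-fold, 2 bounds added after the first was seen. The naming rule required that the 3 vegetative and 8 reproductive libraries not overlap. Of all tested transcripts 8.1% met this, where chance gives 1.21% if all libraries are exchangeable. Reproductive libraries were more alike than vegetative ones, so that chance value is a rough guide only. Quantile normalization changed the split from 70.9% higher among calls to 58.7% (1452 higher, 1020 lower) and moved the median log2 difference of all tested transcripts from 0.04 to -0.07. The 719 lower calls became 1117 without young leaves (1237 higher), 462 without flower bud 3, 460 without flower bud 4, 424 without flower 2, and 284 among transcripts with a mean RPKM of at least 5. A fit on 2 classes called 976 higher and 437 lower.

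**Figure D2:**
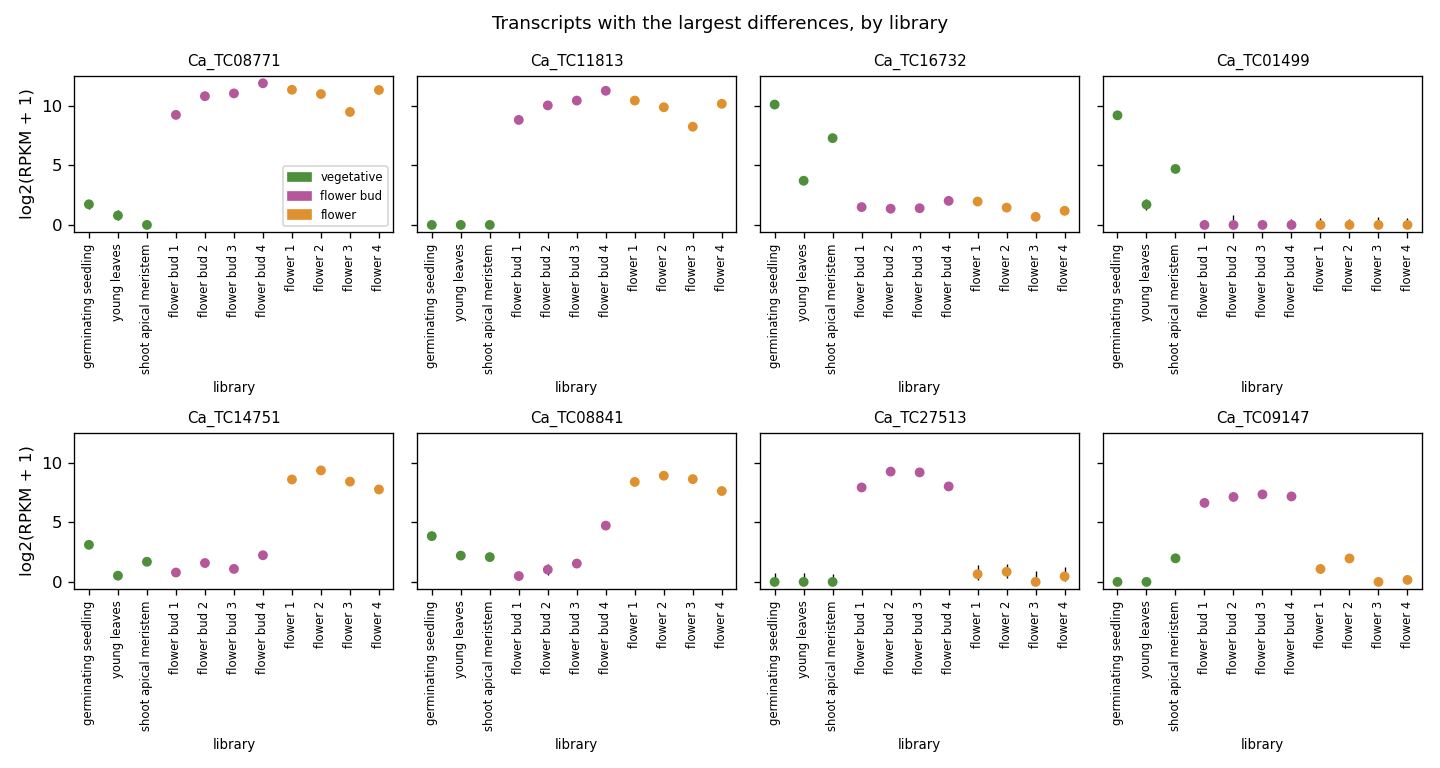
Expression of 8 named transcripts as log2(RPKM + 1) in each of the 11 libraries, coloured by group; points are single libraries and bars are 95% Poisson counting intervals, mostly smaller than the points. Top row, the transcripts named for reproductive against vegetative; bottom row, those named for flower against flower bud.

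In flower buds, 1619 transcripts were higher and 529 lower than in vegetative libraries. Ca_TC11813 was the largest increase, its mean at least 69011-fold above the vegetative floor of 3 reads and flower bud 1, its lowest flower bud, at least 23327-fold. Ca_TC19405 rose from 0.038 ± 0.048 RPKM (SD, n = 3) to 1230 ± 690 (SD, n = 4), a log2 difference of 10.04 ± 0.50 (SE; limma, adjusted p = 4.28e-07). Ca_TC09532 fell from 575 ± 627 RPKM (SD, n = 3) to 3.87 ± 1.15 (SD, n = 4), with -5.75 ± 0.92 on the log2 scale (SE; limma, adjusted p = 0.00309). It had 1261 RPKM in the shoot apical meristem and 29.3 in young leaves. Its log2 difference was -4.595 without that meristem and -7.284 without young leaves. Ca_TC16732 fell by 5.45 ± 1.04 (SE; limma, adjusted p = 0.00867), with -3.917 without the germinating seedling and -7.109 without young leaves. Changes of at least 4-fold numbered 752 higher and 187 lower. Median-of-ratios scaling changed the split from 75.4% higher to 63.6% (1236 higher, 706 lower) and the median log2 difference from 0.10 to -0.05; quantile normalization gave 62.9% (1276 and 754). Leaving out young leaves gave 1167 lower calls, flower bud 2 gave 1010 higher and 282 lower, flower bud 3 gave 945 and 243, and flower bud 4 gave 281 lower. The lower calls were 233 at a mean RPKM of at least 5, and a fit on the 2 classes called 948 higher and 225 lower.

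In flowers, 1990 transcripts were higher and 1060 lower than in vegetative libraries, with 961 and 136 of at least 4-fold. The share of higher calls fell from 65.2% to 55.5% with quantile normalization (1779 higher, 1428 lower) and to 52.5% without young leaves (1442 and 1307), and was 62.4% with median-of-ratios scaling (2129 and 1284). Ca_TC08771 rose by 9.92 ± 0.64 on the log2 scale (SE; limma, adjusted p = 4.8e-06). The flower mean of Ca_TC11813 was at least 48948-fold above the vegetative floor of 3 reads, and flower 3, its lowest flower, at least 15719-fold. Ca_TC16732 fell by 5.70 ± 1.04 (SE; limma, adjusted p = 0.0074), with -4.168 without the germinating seedling and -7.359 without young leaves. Ca_TC10227 fell from 314 ± 467 RPKM (SD, n = 3) in vegetative libraries, of which 851 was in the germinating seedling and 1.22 in young leaves, to 0.417 ± 0.186 (SD, n = 4), a log2 difference of -5.30 ± 1.38 (SE; limma, adjusted p = 0.0322). Flower buds held it at 21.3 ± 5.99 RPKM (SD, n = 4). Its call was lost in limma without the germinating seedling (-3.33 on the log2 scale, adjusted p = 0.0532), the shoot apical meristem (-4.95, 0.0823), or flower 1, 2, 3 or 4 (-5.26, -5.29, -5.26 and -5.39; 0.0636, 0.069, 0.0676 and 0.0581), on 2 classes (-5.30, 0.1) and in voom (-6.74, 0.103), so the difference shrank markedly only without the germinating seedling; over all 20 settings the highest adjusted p was 0.103. Lower calls became 1708 without the germinating seedling, 563 without flower 1, 432 without flower 2 (1192 higher), 525 without flower 3, 597 without flower 4 and 471 at a mean RPKM of at least 5, and a fit on 2 classes called 1070 higher and 312 lower.

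Flower bud and flower shared 675 of their higher and 264 of their lower calls against vegetative tissue. Independent lists of these sizes would share 101.4 and 17.6, and 20 simulations of unchanged groups against shared controls gave 0 in both directions; with no effect almost nothing is called, so that 0 does not measure what shared controls add among called transcripts. The covariance of the log2 differences was 0.652, against 0.112 simulated. The simulation gave every library the spread pooled over the 3 groups. Vegetative tissues were less alike (mean Spearman correlation of 0.771, against 0.917 within flower buds and 0.920 within flowers). The simulated value may therefore understate what shared controls add. With 3 vegetative libraries the controls could not be split, so part of the excess may come from the shared controls.

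Between the reproductive classes, 749 transcripts were higher and 1065 lower in flowers than in flower buds. Ca_TC14751 rose from 1.89 ± 1.32 RPKM (SD, n = 4) to 394 ± 182 (SD, n = 4), a log2 difference of 7.09 ± 0.52 (SE; limma, adjusted p = 3.11e-05). Ca_TC08841 rose from 7.16 ± 12.1 (SD, n = 4) to 347 ± 118 (SD, n = 4), by 6.43 ± 0.77 (SE; limma, adjusted p = 0.00112), and was already at 25.3 RPKM in flower bud 4. Ca_TC27513 fell from 418 ± 198 RPKM (SD, n = 4) to 0.435 ± 0.338 (SD, n = 4), with -8.09 ± 0.34 on the log2 scale (SE; limma, adjusted p = 5.59e-07), and had 0 reads in all 3 vegetative libraries. Ca_TC09147 fell from 134 ± 26.3 (SD, n = 4) to 1.04 ± 1.34 (SD, n = 4), with -6.25 ± 0.51 (SE; limma, adjusted p = 7.8e-05). Of the 1065 lower calls, 174 stayed below 1 RPKM in all 3 vegetative tissues, as did 55 of the 749 higher calls. Among tested transcripts 25.7% separated the 4 flowers from the 4 buds without overlap, where chance gives 2.86% if all these libraries are exchangeable. A gradual change over ordered stages also separates buds from flowers. The excess therefore does not show a step between the classes.

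The direction of the balance between flower and flower bud depended on scaling: 41.3% of calls were higher as deposited, 57.7% with median-of-ratios scaling (1084 higher, 794 lower) and 51.0% with quantile normalization (928 and 892), while the median log2 difference moved from -0.15 to -0.01 with the first. Leaving out flower bud 1 gave 301 higher and 686 lower calls, flower bud 2 gave 241 and 438, and flower bud 3 gave 274 and 483. Leaving out flower 2 gave 375 and 643, flower 3 gave 360 and 568, flower 4 gave 413 and 567, and young leaves 1226 higher. A fit on the 8 reproductive libraries called 1585 higher and 1758 lower.

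Over the 8 reproductive stages in label order, the fitted line rose past the threshold for 2531 transcripts and fell past it for 3893. Ca_TC14751 and Ca_TC08841 had the largest fitted increases, 9.49 ± 1.80 (SE; limma, adjusted p = 0.00972) and 9.45 ± 1.49 (SE; limma, adjusted p = 0.00561) on the log2 scale. Ca_TC27513 and Ca_TC29532 had the largest fitted decreases, -10.89 ± 1.98 (SE; limma, adjusted p = 0.00841) and -8.63 ± 1.88 (SE; limma, adjusted p = 0.0149). These are ends of a straight line and exceed the measured changes. From flower bud 1 to flower 4, Ca_TC27513 went from 240 to 0.37 RPKM and Ca_TC14751 from 0.73 to 213. Stage order and class run together, so a step between flower bud and flower also gives a slope. Ca_TC29532 had 85.9, 306 and 118 RPKM in flower buds 1 to 3 and 0.45 or less from flower bud 4 on. Stage number within class was fitted in limma as 1 slope shared by flower buds and flowers, with class as a covariate. It gave 0 calls and 2359 transcripts at an unadjusted p under 0.05, a level that chance gives for 0.05 of the 31776 tested. None of the 4 named transcripts passed (limma, adjusted p of 0.699 to 0.985), while the other 16 settings of Ca_TC14751 kept its call. A shared slope can miss changes that differ between flower buds and flowers. The 0 calls therefore do not show that expression was constant within a class. Median-of-ratios scaling turned the split from 39.4% to 59.1% rising (3294 up, 2278 down) and the median from -0.26 to -0.01, and the falling calls were 2434 without flower bud 1, 2139 without flower bud 2, 2305 without flower 3 and 2541 at a mean RPKM of at least 5.

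Expression changed unevenly from stage to stage. Differences of at least 2 in log2(RPKM + 1) numbered 556 from flower bud 1 to 2, 212 from bud 2 to 3, 419 from bud 3 to 4 and 555 from bud 4 to flower 1. From flower 1 to flower 2 there were 23, followed by 946 from flower 2 to 3, where 432 were higher and 514 lower, and 525 from flower 3 to 4. With median-of-ratios scaling the step from flower 2 to 3 had 514 higher and 411 lower. Each step compares 2 single libraries and has no replicate check.

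**Figure D3:**
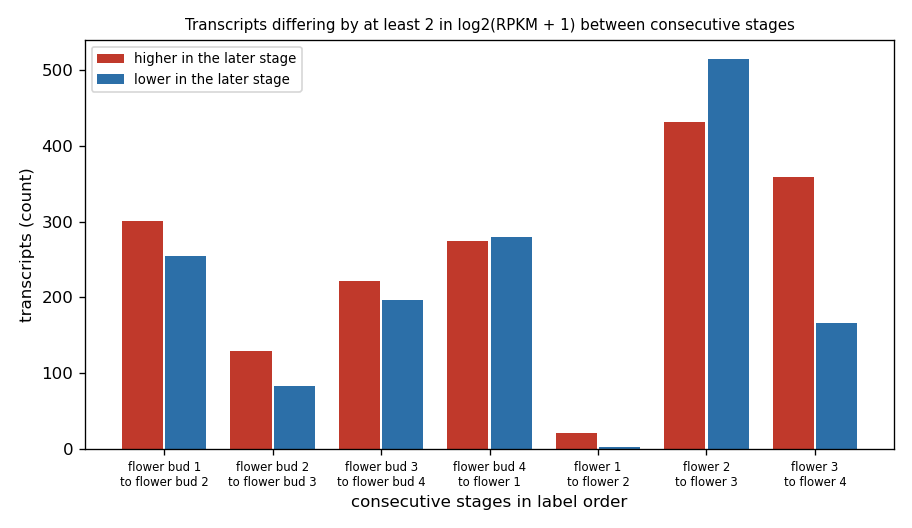
Number of transcripts (y axis) whose log2(RPKM + 1) differed by at least 2 between consecutive stages in label order (x axis), higher in red and lower in blue. The step from flower 1 to flower 2 holds 23 transcripts and that from flower 2 to flower 3 holds 946.

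Tissue-specific expression, the other question named in the series text, was concentrated in few libraries. Of 782 library-specific transcripts, 395 belonged to the germinating seedling, 194 to the shoot apical meristem, 108 to flower bud 1 and 69 to young leaves. The other 7 reproductive libraries held between 0 and 9 each, and flower 3 had the 9. Median levels were 24.4 RPKM in the germinating seedling against 1.69 in the next library, 44.2 against 5.85 in the shoot apical meristem, 30.9 against 2.43 in flower bud 1 and 36.3 against 3.82 in young leaves. A transcript at like levels in 2 sampled stages cannot be library-specific by this definition, so the counts also depend on which neighbouring stages were sampled. Requiring 10 times the next library left 346 and changed the order: 216 in the germinating seedling, 74 in flower bud 1, 37 in the shoot apical meristem and 15 in young leaves.

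Reproductive-only expression, under 0.1 RPKM in each vegetative tissue, was found for 164 transcripts, of which 112 had 0 reads in all 3 vegetative libraries and 45 reached 1 RPKM in all 8 reproductive ones. Their median highest level was 41.8 RPKM. They peaked in buds more often than in flowers, 115 against 49, with 44 in flower bud 4 and 31 in flower bud 1. Of these, 50 reached 1 RPKM in buds and in no flower, and 2 the reverse. The mirror criterion gave 2 vegetative-only transcripts, Ca_TC01499 and Ca_TC34689, the second named here after its values were seen; it had 290 RPKM in the germinating seedling, 21.1 in the shoot apical meristem and 2.19 in young leaves. The vegetative criterion asked for all 3 tissues and the reproductive one for any 3 of 8 libraries, so the counts are not on 1 scale. At the median length, 3 reads equal 0.17 RPKM in the germinating seedling, 0.15 in young leaves and 0.13 in the shoot apical meristem. The limit of 0.1 RPKM lies below these floors, so meeting it depends on transcript length and depth. Allowing up to 0.5 RPKM in the other class gave 410 and 12.

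Of the 1748 transcripts higher in reproductive libraries, 384 (22.0%) were highest in flower bud 4, the largest share of the 8 stages. Flower 3 followed with 246 and flower 4 with 230, and flower bud 1 had the fewest, 136. Median-of-ratios scaling gave 385 for flower bud 4 and 332 for flower 3.

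**Figure D4:**
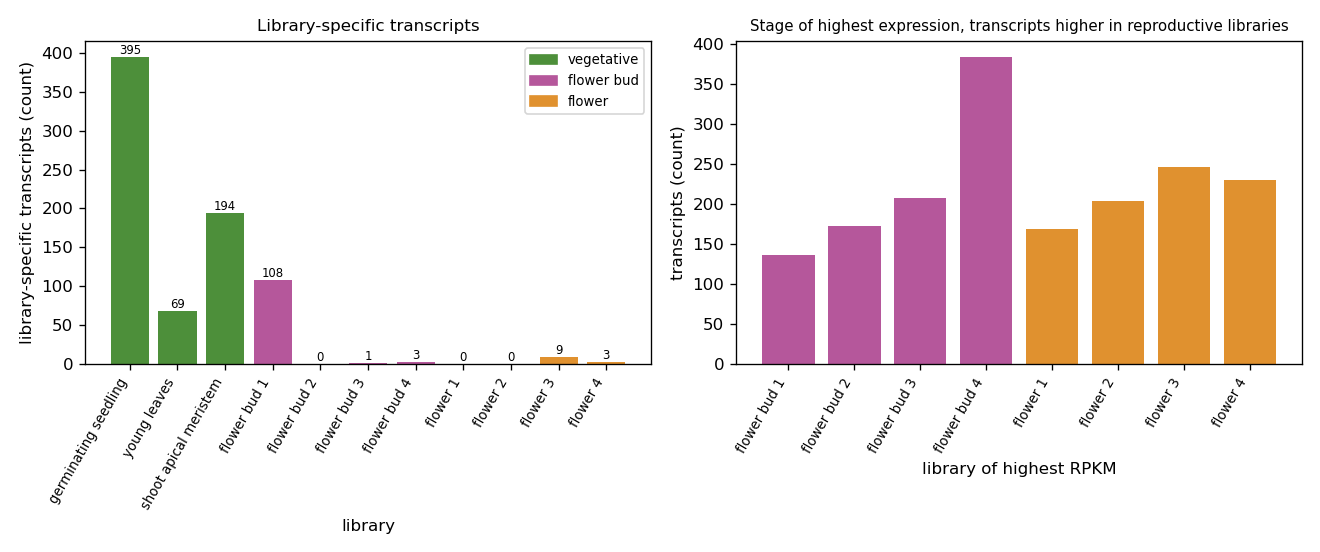
Left, library-specific transcripts (count) in each of the 11 libraries; right, the reproductive library with the highest RPKM for the 1748 transcripts higher in reproductive than vegetative libraries. Flower bud 1 has 108 library-specific transcripts on the left, and flower bud 4 holds 384 peaks on the right.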

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

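The tests on flower bud 1 were all chosen after its count of 108 was seen; for the test on flower bud 2 levels the deciding value had been seen too, and for depth and a constant source it had not. The comparison with transcripts in general was added when both values were known. Of 34 groups checked for a library far from the rest, 2 stood out, where chance gives about 1.7.

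Flower bud 1 stood far from the other flower buds in library-specific transcripts, with 108 against 0, 1 and 3. Depth does not account for this, since after thinning all libraries to 14536530 reads the count was 107, while the highest of the other 7 reproductive libraries was 8. Reads from 1 other source of constant makeup stay open: the flower bud 2 share of reads varied with a median squared deviation 12.83 times its Poisson value, but the value for these 2 libraries over transcripts in general was 12.95. Flower bud 2 was the next highest library for 73 of the 108 (67.6%). Expression that declines after the youngest sampled bud would give this, a hypothesis found and tested on the same libraries. Flower bud 2 was also the library most like flower bud 1 across all transcripts (Spearman correlation of 0.920). The count therefore does not decide between this hypothesis and others. Other tissue in flower bud 1 alone, and a difference between the sampled plants, stay open as well with 1 library per stage.

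Ca_TC08841 had 25.3 RPKM in flower bud 4 against 0.408, 1.04 and 1.90 in the other flower buds, far from the rest of its group and below the 195 to 474 RPKM of the 4 flowers.

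The change against vegetative tissue went in opposite directions in flower bud and flower for 1 transcript each way, both past the threshold for the difference between flower and flower bud; both were named after their values were seen. Ca_TC05206 had 16.5 ± 1.67 RPKM (SD, n = 3) in vegetative libraries, 38.9 ± 5.56 (SD, n = 4) in flower buds and 6.24 ± 1.26 (SD, n = 4) in flowers, with -2.47 ± 0.21 between flower and flower bud (SE; limma, adjusted p = 8.97e-05). Ca_TC16534 had 22.3 ± 8.05 (SD, n = 3), 9.55 ± 1.34 (SD, n = 4) and 75.5 ± 14.99 (SD, n = 4), with 2.85 ± 0.24 (SE; limma, adjusted p = 8.97e-05).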

How the results depend on the processing

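Limma voom on recovered reads and the filters on reads and thinned libraries were chosen after seeing the data. Class separation was past its threshold in both alternatives. The pseudocount of 0.1, no filter, quantile normalization, no intensity trend, voom and the filter on recovered reads left every count of calls within 1.5 times its value. No called transcript changed sign under any setting except the stage number within class, where 276 did. Voom called 1426 higher and 723 lower for reproductive, 1444 and 463 for flower bud and 1843 and 971 for flower against vegetative, 628 and 969 for flower against flower bud, and 2489 and 4063 over the stages. Of the named transcripts, Ca_TC10227 lost its call in 8 of 20 settings and the 4 of the stage order in 1. The rest kept theirs wherever they were tested. Ca_TC01499 was tested in 17 of 20 settings. It failed the filter of 3 libraries when any vegetative tissue was left out, so its call was not checked there. Ca_TC29532 was tested in 14 of the 17 settings of the stage order, and failed that filter without flower bud 1, 2 or 3.

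Apart from the block given below, the following counts moved by over 1.5 times, and the cause was not tested except where stated. At a mean RPKM of at least 5, lower calls were 284 for reproductive, 233 for flower bud and 471 for flower against vegetative, and 2541 fell over the stages. Of the 2467 reproductive calls in both directions, 1789 were still tested there, and 1776 of those kept their call. The reproductive calls lost were therefore mostly transcripts that this filter left out. Fits on 2 classes gave 976 higher and 437 lower for reproductive, 948 and 225 for flower bud, 1070 and 312 for flower, and 1585 and 1758 for flower against flower bud. These fits leave the log2 differences unchanged, so the counts moved with the estimate of the spread and the libraries behind it. Median-of-ratios scaling gave 2278 falling over the stages, and the stage number within class 0 rising and 0 falling (limma; 2359 at an unadjusted p under 0.05). With 10 times the next library 346 transcripts were library-specific; with up to 0.5 RPKM in the other class 410 were reproductive-only and 12 vegetative-only; with a difference of at least 1 the steps numbered 23220.

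Leaving out each library in turn gave 1237 to 2153 higher and 424 to 1117 lower calls for reproductive, 945 to 2162 and 243 to 1167 for flower bud, and 1192 to 2646 and 432 to 1708 for flower against vegetative. It gave 241 to 1226 higher and 438 to 1503 lower for flower against flower bud, and 1700 to 2401 rising and 2139 to 3511 falling over the stages. Without young leaves 52.5% of reproductive calls were higher, against 70.9%.

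Stage numbers are shared by flower bud and flower. Same-numbered libraries did not deviate together (correlations across transcripts of -0.20, -0.15, -0.08 and -0.13), so the numbers do not pair the samples, and no library correlated best with its own number. Stage number as a replicate block, fitted on the 8 reproductive libraries, gave 1176 higher and 1293 lower for flower against flower bud. That is over 1.5 times the 749 higher of the 3-group fit, but fewer than the 1585 and 1758 of the same 8 libraries without the block.

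Differences that were never past the threshold changed sign. In detected transcripts, the following signs differed from the main ones: reproductive minus vegetative was 643 at an RPKM of at least 5 and 61.8 after thinning, flower bud minus vegetative -71.4 and flower minus flower bud 50.5 at an RPKM of at least 0.1, and flower minus vegetative 43.1 at an RPKM of at least 5. Leaving out libraries spanned -1016 to 487, -768 to 736 (flower bud) and -1265 to 239 (flower) against vegetative. In the share of the 100 highest it spanned -11.49 to 0.58 for reproductive and -10.24 to 1.83 for flower minus vegetative. At the depth of flower bud 2, 3 reads in a transcript of median length equal 0.28 RPKM, so absences under that level were not detectable there.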

Other observations

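The tests over other splits of the libraries were chosen after their results were seen; those on abundant transcripts, length and repeated deposits were set before their values were computed, though related values had been seen. Leaving out single libraries in the tests on abundant transcripts and length, and the other rankings, were added when the first values were known. The transcripts below were picked after their values were seen.

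Most of the 10 most abundant transcripts were lower in flower bud 4 than in its neighbours. Among the 10 with the highest mean RPKM over the 11 libraries, 8 were lower in flower bud 4 than in both flower bud 3 and flower 1; median-of-ratios scaling also gave 8, as did ranking without young leaves. High levels in flower bud 3 or flower 1 help a transcript into this set, and ranking on the 8 other libraries alone gave 7 of 10. Among all tested transcripts, 8215 (25.9%) were lower in flower bud 4 than in both neighbours. The count among the 10 was not tested against chance. Ca_TC23009, the highest by mean, went the other way, with 8293 RPKM in flower bud 3, 9332 in flower bud 4 and 5712 in flower 1. Together the 10 summed to 56476 RPKM in flower bud 3, 28836 in flower bud 4, 100419 in flower 1 and 24559 in flower 4, and to 146831 in young leaves. In flower 1 they took 3.79% of reads and in flower bud 1 0.89%.

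The vegetative-only transcripts Ca_TC01499 and Ca_TC34689 ranked the tissues alike: 578 and 290 RPKM in the germinating seedling, 24.8 and 21.1 in the shoot apical meristem, and 2.26 and 2.19 in young leaves. Ca_TC11813 and Ca_TC19405 both had their highest level in flower bud 4, 2406 and 2174 RPKM, and their lowest reproductive level in flower 3, 298 and 341; in flower bud 1 they had 443 and 537.

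The balance of higher and lower calls between flower and flower bud moved with scaling. A few abundant transcripts taking the reads does not account for it: without the 100 highest transcripts, and rescaled to the remaining reads, the median log2 difference was -0.14, against -0.15 with them. Leaving out each reproductive library in turn kept this median between -0.17 and -0.11. Transcript length bias stays open: the medians were -0.16 up to 432 bases, -0.10 between and -0.19 above 1243 bases, and the longest minus the shortest group was -0.03, with -0.06 to 0.02 when single libraries were left out. A broad shift of many transcripts, biological or from library preparation, stays open too.

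Flower 1 and flower 2 were the most alike pair, with a Spearman correlation of 0.976 and 23 transcripts changed by at least 2. A single library deposited 2 times is argued against, since over 28086 transcripts their reads differed with a median squared deviation 4.25 times its Poisson value. For the other consecutive stages this value ran from 6.69 to 24.39. Close sampling times or similar tissue may explain the likeness, and neither was tested.

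No other split of the libraries that was tried gave as many calls as the real classes. For flower bud against vegetative, 1 of the 35 splits, the real one, gave as many calls (2148; the highest other 317). For flower against vegetative 1 of 35 did (3050; 51), and for flower against flower bud 1 of 35 (1814; 157). For reproductive against vegetative in a fit on 2 classes, 1 of 100 splits did, drawn from 165 (1413; 238). Every other split mixes classes, which adds the class difference to the spread within groups, so few calls were likely there from the start. With few splits, and tests chosen after their results were seen, chance is not excluded. The counts speak of differences between these libraries and not of replicate plants.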
